A study of Homo sapiens with 7 samples.

How the data were processed

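RNA from human bone marrow mesenchymal stem cells, bought from a supplier per the labels' protocols, was measured on 7 Affymetrix 3' expression arrays. After attachment the cells had been moved to medium without serum and given kartogenin at 1, 10 or 100 nM, or the solvent DMSO alone, for 6 or 24 h. There was 1 array for each of the 6 combinations of dose and time and 1 DMSO array, whose label gives no time. Labelled cRNA was made with a 3' in vitro transcription kit, per the labels' protocols.

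The deposited values are array intensities on a linear scale, made with GCRMA under R 2.8.0 per the submitters' processing notes. Further settings of that step are not given in the sources used here. GCRMA removes background with a probe sequence model and brings the arrays to common quantiles before summarising probes, which leaves a shared lowest value and can shrink or stretch differences of dim genes near it. The lowest deposited intensity was 4.777 (2.26 on the log2 scale) and the highest 76694, and between 34.2% and 37.1% of the probe sets of an array lay at the lowest value. The number of arrays, not a read depth, limits the precision.

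The log2 of the deposited intensity was analysed with no further normalization. Of 54675 probe sets, 41097 had 1 gene symbol in the platform annotation, 1801 had several and 11777 had none listed, and the last 2 kinds were left unnamed. Symbols were updated through Entrez identifiers against the GRCh38.p14 gene table for 41043 probe sets, and 54 kept their older symbol. The build behind the array's probes was not used here, so no coordinates are given. Each of 19775 genes was represented by its probe set with the highest mean log2 intensity, and the 9383 genes with a mean of at least 5 were tested. Genes on the Y chromosome and XIST are not reported, and the ratio of a further set of control probe sets is not reported here.

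Changes were tested with limma 3.58.1 under R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05 over the genes tested). The time effect was 24 h minus 6 h over the 6 kartogenin arrays with dose as a factor (2 residual degrees of freedom). The dose trend was the slope per 10-fold dose with time as a factor (3 residual degrees of freedom), and its difference between times was tested with a product term (2 residual degrees of freedom). Each time was set against DMSO in a fit of all 7 arrays in 3 arms (4 residual degrees of freedom), so the doses within a time supplied the spread and the lone DMSO array was assumed to vary like the treated arrays. No group held a second array, and nothing in the labels says whether the wells were separate cultures, so p-values measure only the spread between these arrays, which may be technical. A dose effect adds to that spread in the DMSO comparisons. In the time comparison, with dose as a factor, only a dose effect that differs between times does. Errors printed with a log2 change are moderated standard errors, and SDs are over the 3 doses of a time. Single arrays were compared with DMSO by counts of genes differing by at least 1 on the log2 scale, with no test.

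Before the data were examined, 31 gene lists were fixed, covering cartilage, bone, fat, matrix, signalling, stress, metabolic and cell cycle genes, reference genes, and markers of mesenchymal, blood and endothelial cells. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 29 lists that held at least 3 tested genes. The median of each list was also ranked among 10000 random lists matched on mean expression. With the estimated correlation, 0 lists passed in any comparison. The genes named are those fixed before the data were examined: the 10 largest rises and 10 largest falls among genes past the threshold with the same sign at all 3 doses, for the time effect and both DMSO comparisons, the 3 smallest p each way for the dose tests when none passed, 15 fixed genes of cartilage and of the RUNX and CBF-beta pathway, and the largest changes within lists. Of the 15, RUNX1 is not reported because its 13 probe sets each list several symbols, and FLNA because no probe set carried that symbol in the annotation used.

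The fits were tested on simulated data with 200 changed genes among 9383. For a log2 change of 1, 97.0% were recovered for the time effect, 90.5% for the dose trend (change from 1 to 100 nM), 88.0% for 6 h against DMSO and 88.5% for 24 h against DMSO, with 7 to 9 false calls. The simulated spread was drawn from the moderated residual variances. It was independent between genes and equal on all 7 arrays, DMSO included, with no shift of whole arrays. The rates therefore hold for such data, and they do not test the assumption about the lone DMSO array. Alternatives covered the filter on dim genes, the probe set per gene, normalization, the variance model, a size threshold, the form of the dose term, the arms in the fit and leaving out arrays. Fits without the 10 nM and 1 nM arrays at 24 h, a fit of the dose trend at 6 h alone and fits with the actin 3' to 5' ratio as a covariate were chosen after seeing the data.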

Results

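Kartogenin is a small molecule studied for its ability to drive mesenchymal stem cells toward cartilage, and the study's title ties it to CBF-beta, the partner subunit of the RUNX transcription factors. Expression was profiled on 7 arrays of human bone marrow mesenchymal stem cells, with 1 array each for 1, 10 and 100 nM at 6 h, 1, 10 and 100 nM at 24 h, and the DMSO vehicle. No condition was replicated. The design asks how expression changed with treatment, with time and with dose, and 9383 expressed genes were compared.

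Arrays of the same time resembled each other more than arrays of different times. Over the tested genes the root mean square log2 difference was 0.14 to 0.16 between the 6 h arrays, 0.23 to 0.28 between the 24 h arrays and 0.39 to 0.56 between a 6 h and a 24 h array. The first principal component held 72.2% of the variance and placed DMSO at -33.6, the 6 h arrays between -17.6 and -12.5, and the 24 h arrays between 19.9 and 33.5. The control probe sets also differed between arrays. The ratio of the 3' to the 5' actin probe set, which rises as cRNA becomes shorter, was 3.22 on the DMSO array and 3.94 to 4.74 at 6 h, and at 24 h it was 5.42 at 100 nM, 8.97 at 10 nM and 13.55 at 1 nM. The BioB hybridization spike-ins were 1.32 to 1.37 times the DMSO level at 6 h, and at 24 h 1.53 times at 100 nM, 2.45 times at 10 nM and 3.35 times at 1 nM. The 18S ribosomal RNA control had an intensity of 5721 with DMSO, 891 to 1260 at 6 h, 1379 at 100 nM and 24 h, and 7569 and 6510 at 10 and 1 nM and 24 h. The GAPDH ratio stayed between 1.05 and 1.18.

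**Figure D1:**
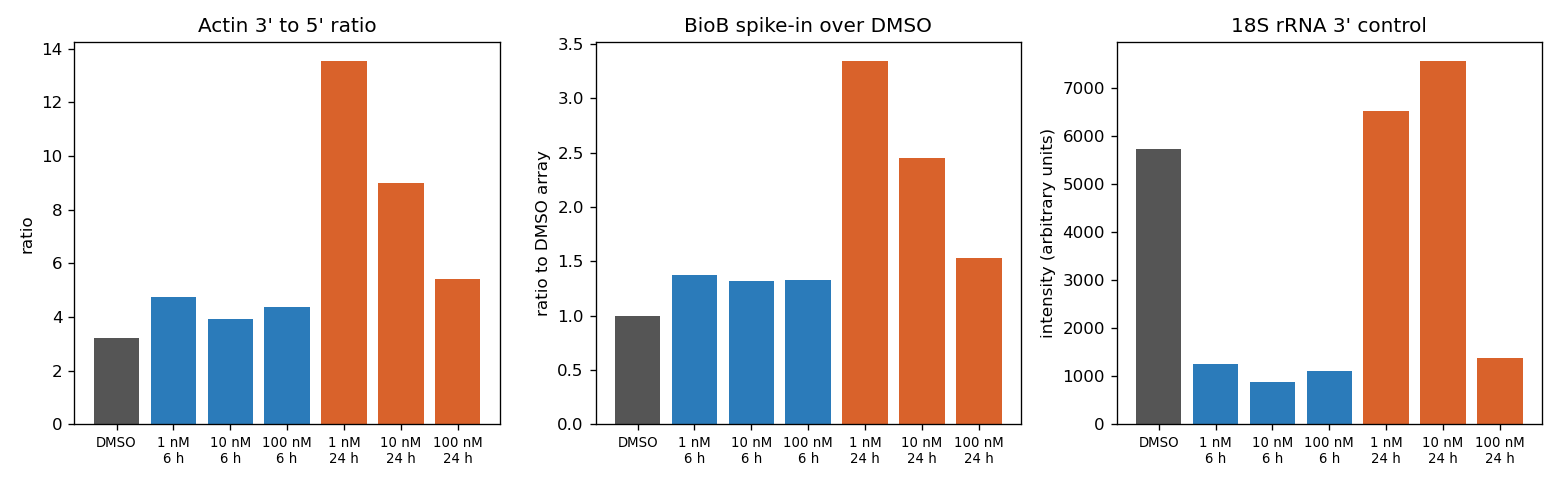
Control probe sets on each array (x axis: vehicle, dose and time): the actin 3' to 5' ratio, the BioB spike-in intensity relative to the DMSO array, and the 18S ribosomal RNA intensity in arbitrary units, 1 bar per array with no error. The actin ratio and the spike-ins were highest on the 1 nM array at 24 h, at 13.55 and 3.35.

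Among genes more than 1 log2 unit above the lowest value with DMSO, ANGPTL4, a secreted regulator of lipoprotein lipase, had the largest rise at 6 h. It was bright in every array and rose 15.8-fold, from 8.84 with DMSO to 12.82 ± 0.29 (log2, SD over 3 doses). RIPK4, the tight junction protein CLDN14, PPP1R14C, the MAP kinase phosphatase DUSP4 and neuromedin B (NMB) rose by 3.86, 3.59, 2.96, 2.89 and 2.82 on the log2 scale. The next 4 genes also rose but lay within 1 log2 unit of the lowest value with DMSO, so their fold is not given or ranked. NFATC2, a calcium-regulated transcription factor, stood at 3.02 with DMSO and 9.35 ± 0.35 at 6 h (adjusted p = 0.00195), and HSPA6, an inducible heat shock protein, at 2.66 and 6.87 ± 0.20 (adjusted p = 0.00258). TGFB3, a growth factor that induces cartilage formation, stood at 3.25 and 7.25 ± 0.32 (adjusted p = 0.00658), and BMP2, a bone and cartilage morphogen, at 2.97 and 6.59 ± 0.33 (adjusted p = 0.00725). The largest falls were smaller. The hair keratin-associated genes KRTAP1-3, KRTAP1-5 and KRTAP1-1, close copies whose signals the probes may not separate, changed by -1.76, -1.57 and -1.45. The change was -1.75 for CARMN, -1.74 for FILIP1L, -1.59 for LOC100190986, -1.45 for ANKRD1, a target of YAP signalling, -1.44 for the growth factor FGF7, -1.40 for ZSCAN26 and -1.30 for the interferon-induced gene IFIT1.

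In all, 1080 genes passed the threshold at 6 h, 674 higher and 406 lower, each with the same sign at all 3 doses. Of these, 180 were at least 2-fold higher and 20 at least 2-fold lower. The count rests on few arrays, and was 190 without the 10 nM and 277 without the 100 nM array of that time and 695 without the 1 nM array. Leaving out the 10 nM array at 6 h ended the calls of CARMN, FILIP1L, KRTAP1-1, KRTAP1-3, ANKRD1, FGF7, ZSCAN26, IFIT1 and LOC100190986 (lowest adjusted p = 0.0524 for LOC100190986, highest 0.137 for FGF7). The split of the calls was 479 higher and 519 lower with no filter on dim genes, and 404 and 412 with the mean of the probe sets of each gene.

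Genes of hypoxia and glycolysis led the lists that moved at 6 h. Of 17 tested, 9 rose, 0 fell and 8 did not pass (10 rose when adjusted over the list alone), among them PFKFB3, a regulator of glycolysis, by 1.86, the peptide ADM by 1.67, NDRG1 by 1.67 and the glucose transporter SLC2A3 by 1.46. The list's camera adjusted p was 3.87e-05, and its median of 0.62 lay at percentile 100 of matched random lists. Of 15 NF-kB and inflammatory genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with CXCL3 up by 2.22, TNFAIP3 by 1.75 and CXCL8 by 1.69 (camera adjusted p = 0.00138). The gene that fell, named after its values were seen, was the chemokine CCL2, at -0.80. Of 22 immediate early genes, which answer growth signals, 7 rose and 2 fell (9 and 2 adjusted over the list alone), with DUSP5 up by 2.21, FOSL1 by 2.01 and SPRY4 by 1.54 (camera adjusted p = 0.0218). Of 12 mesenchymal surface markers 4 rose (6 adjusted over the list alone), with PDGFRB up by 1.07 and ITGA5 by 0.67. Of 14 hypertrophic cartilage genes 5 were tested and 3 rose (4 adjusted over the list alone), namely RUNX3 by 1.09, VEGFA by 1.08 and MEF2C by 0.86. The surface marker and hypertrophic lists had camera adjusted p = 0.00138 and 0.00187. COL10A1 and MMP13 of the hypertrophic list were too dim to be tested, and VEGFA is also in the hypoxia list. The lists of fibrillar matrix (3 of 22 higher, also 3 adjusted over the list alone, FBLN1 by 0.37 and COL6A3 by 0.32, adjusted p = 0.00187), circadian genes (4 of 11 higher, 5 adjusted over the list alone, BHLHE40 by 1.13 and RORA by 1.10, adjusted p = 0.0218), protease inhibitors (1 of 8 higher, TIMP2, also 1 adjusted over the list alone, adjusted p = 0.0433) and FOXO and quiescence genes (3 of 18 higher and 1 lower, 6 and 1 adjusted over the list alone, BCL6 up by 1.29 and CITED2 down, at -0.77, adjusted p = 0.0433) also passed as groups. All 9 calls were lost with an estimated correlation, each list having adjusted p = 0.357 with an estimated correlation. The protease inhibitor call was also lost with quantile normalization (adjusted p = 0.055), and the circadian, FOXO and immediate early calls when the 24 h arrays at 10 and 1 nM were left out of the fit (adjusted p = 0.0764, 0.0531 and 0.0998). Beside these groups, the actin ratio was 3.94 to 4.74 on the 6 h arrays and 3.22 on the DMSO array.

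The chondrogenic list did not pass at 6 h (camera adjusted p = 0.0563). Of its 11 tested genes 3 rose, both over all genes and adjusted over the list alone: SOX9, the master regulator of cartilage, CHST11, a chondroitin sulfotransferase, by 0.91, and WWP2 by 0.49. Lists that did not pass held single large changes. In the TGF-beta and BMP list 5 of 21 rose and 2 fell (7 and 5 adjusted over the list alone), with PMEPA1 up by 1.52 and TGFB1 by 0.99. HMOX1 rose by 1.93 in the NRF2 and AHR list, whose mean was 0.22 and median -0.09. DDIT4 rose by 2.41 and DDIT3 by 1.54 among 18 stress genes, of which 3 rose and 4 fell, and that list had a mean of 0.09, a median of -0.06 and a camera direction downward. The adipogenic list had a mean of 0.08 and a median of -0.02. INSIG1 rose by 1.07 in the cholesterol list and SCD by 1.00 in the fatty acid list.

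At 24 h more genes passed in the same comparison. The label of the DMSO array gives no time, so at 24 h as at 6 h kartogenin and time in medium without serum cannot be told apart. HES4, a transcriptional repressor induced by Notch signalling, was 5.81 ± 0.24 higher than with DMSO (adjusted p = 0.000344). NMB rose by 4.87, CLDN14 by 4.67, ANGPTL4 by 4.55 and the lipid droplet protein HILPDA by 4.40. HEY1, a related repressor at 2.55 with DMSO, lay within 1 log2 unit of the lowest value there, as did HSPA6, NFATC2, TGFB3 and BMP2, so their fold is not given or ranked. They passed at 24 h with means of 6.88 ± 0.05 for HEY1, 9.98 ± 0.23 for HSPA6, 8.21 ± 0.19 for NFATC2, 8.38 ± 0.41 for TGFB3 and 7.58 ± 0.41 for BMP2 (highest adjusted p = 0.000868 for BMP2). The largest falls were -3.27 for KRTAP1-3, -3.22 for FILIP1L, -3.19 for the phosphatase UBASH3B, -3.18 for KRTAP1-5, -2.99 for IFIT1, -2.91 for KRTAP1-1, -2.91 for LCMT2, -2.77 for CCNYL1, -2.61 for CARMN and -2.59 for TEFM, a mitochondrial transcription elongation factor. KRTAP1-5 was bright, at 12.67 with DMSO and 9.50 ± 0.04 (SD over 3 doses) at 24 h.

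The threshold was passed by 3886 genes at 24 h, 1457 higher and 2429 lower, and 353 and 514 of them differed by at least 2-fold. The median over all genes was -0.09, and centring each array on its median changed the split to 2017 higher and 1890 lower. Fitted with only its own arm and DMSO the count was 1593, and the calls of TEFM, CARMN and the mitotic gene ASPM ended (adjusted p = 0.0715, 0.0512 and 0.0553). With the actin ratio as a covariate the count was 1445, and those of TEFM and ASPM ended (adjusted p = 0.0844 and 0.0678), at changes of -1.49 and -2.06. Without the 24 h arrays at 10 and 1 nM, whose actin ratios were highest, it was 3313, of which 2736 were among the 3886. This sets 1 array at 24 h against 1 DMSO array with the spread taken from the 6 h arrays.

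The inflammatory list passed again at 24 h. Of 15 genes, 12 were higher and 1 lower than with DMSO (12 and 2 adjusted over the list alone), with CXCL3 up by 3.90, CXCL8 by 3.42 and IL11 by 2.60 and CCL2 the gene that fell, at -1.92 (camera adjusted p = 4.33e-05, and adjusted p = 0.282 with an estimated correlation). Of the 17 hypoxia and glycolysis genes 11 were higher and 0 lower (11 adjusted over the list alone), with SLC2A3 up by 2.48, NDRG1 by 2.45 and ADM by 2.31 (camera adjusted p = 3.48e-05, and adjusted p = 0.282 with an estimated correlation). Mitotic genes fell. Of 18 G2/M genes 13 were lower and 0 higher (14 lower adjusted over the list alone), including ASPM at -2.21, CDC20 at -1.79, DLGAP5 at -1.66 and CCNB1 at -1.58 (camera adjusted p = 0.000334, and adjusted p = 0.225 with an estimated correlation). Of 16 S-phase genes 8 were lower (also 8 adjusted over the list alone), including UHRF1 at -1.35 and PCNA at -1.02 (camera adjusted p = 0.0385, and adjusted p = 0.282 with an estimated correlation). Of 18 FOXO and quiescence genes 9 were higher and 2 lower (11 and 2 adjusted over the list alone), with BCL6 up by 1.85, FBXO32 by 1.5 and CCNG2 by 1.43 and CITED2 at -1.57 (camera adjusted p = 0.00134, and adjusted p = 0.225 with an estimated correlation). Beside each of these groups, the actin ratio was 5.42 to 13.55 on the 24 h arrays and 3.22 on the DMSO array.

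Further lists passed at 24 h. Among 9 tested genes of cartilage breakdown 7 rose and 2 fell, over all genes and adjusted over the list alone, with the collagenase MMP1 up by 2.56 and MMP14 by 1.36 and the aggrecanases ADAMTS1 and ADAMTS5 at -1.36 and -0.97 (camera adjusted p = 0.0325, and adjusted p = 0.46 with an estimated correlation). Of 8 protease inhibitors 3 rose (also 3 adjusted over the list alone), led by TFPI2 at 2.08, with camera adjusted p = 0.0325 (adjusted p = 0.282 with an estimated correlation). In the adipogenic list 6 of 16 genes were tested and 3 rose (also 3 adjusted over the list alone), namely CEBPB by 1.44, PLIN2 by 0.82 and ADIRF by 0.47 (camera adjusted p = 0.0127, and adjusted p = 0.46 with an estimated correlation). Of 14 hypertrophic genes 5 were tested and 4 rose (4 higher and 1 lower adjusted over the list alone), with RUNX3 at 1.19 and VEGFA, also in the hypoxia list, at 1.06 (camera adjusted p = 0.0232, and adjusted p = 0.282 with an estimated correlation). Of 8 genes in the metallothionein list 5 rose and 1 fell (the same counts adjusted over the list alone), with MT1X at 0.73 (camera adjusted p = 0.0157, and adjusted p = 0.282 with an estimated correlation). The gene that fell, at -0.44, was the zinc exporter SLC30A1, which is not itself a metallothionein. Whether the probes separate the signals of the metallothionein genes was not tested. Fibrillar matrix genes (5 of 22 higher, also 5 adjusted over the list alone, COL6A2 by 0.69) had camera adjusted p = 0.0385 (adjusted p = 0.501 with an estimated correlation), and ribosomal protein genes (1 of 13 higher, 0 adjusted over the list alone) 0.0232 (adjusted p = 0.282 with an estimated correlation). The medians of the matrix and ribosomal lists lay at percentiles 81.8 and 89.1 of matched random lists. Those of the other lists that passed at 24 h lay at 0.65 or lower or at 97.68 or higher. With quantile normalization the calls of the breakdown, protease inhibitor, metallothionein, S-phase, matrix and ribosomal lists were lost, and without the 24 h arrays at 10 and 1 nM, which leaves 1 array at that time, those of the breakdown, S-phase and hypertrophic lists (adjusted p = 0.0722, 0.0874 and 0.0589). With no filter on dim genes the hypertrophic call was also lost (adjusted p = 0.0834). Beside these lists the BioB spike-ins were 1.53 to 3.35 times the DMSO level.

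Lists that did not pass at 24 h included the chondrogenic genes, of which 3 rose and 1 fell among 11 (camera adjusted p = 0.158), and the RUNX, CBF-beta and filamin list, with 2 higher and 3 lower of 9 (adjusted p = 0.743). In the TGF-beta and BMP list 6 rose and 10 fell of 21 (adjusted p = 0.746), and its mean of 0.22 and median of -0.27 differed in sign. TGFB1 rose there by 1.93 and the BMP target ID1 was at -1.90. Of 10 NRF2 and AHR genes 2 rose and 7 fell, of 18 stress genes 5 rose and 6 fell with DDIT3, a mediator of the unfolded protein response, at 3.89, of 14 contractile genes 0 rose and 5 fell, and of 12 mesenchymal surface markers 5 rose and 3 fell, with CD9 at 1.34 and PDGFRA at -0.61. Of 22 immediate early genes 9 rose and 6 fell, of 11 circadian genes 4 rose and 2 fell, of 13 p53 targets 5 rose and 3 fell, of 9 heat shock genes 4 rose and 2 fell, of 4 osteogenic genes 2 rose, of 6 hyaluronan genes 3 rose and 2 fell with HAS2 at -1.94, of 5 interferon genes 1 rose and 2 fell, of 14 cholesterol genes 2 rose and 2 fell, and of 8 fatty acid genes 1 rose and 1 fell. Of 11 reference genes 2 rose and 1 fell, TFRC at -0.89. Mean and median also differed in sign for the hyaluronan, interferon and fatty acid lists, and the camera direction was upward against a negative median for the cholesterol and reference lists. The lists of blood cell and endothelial markers had 1 expressed gene each, LAPTM5 and TEK, at 0.65 and -0.01 with adjusted p = 0.0543 and 0.944. LAPTM5 passed over its list alone, but with 1 tested gene that is the unadjusted limma p.

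**Figure D2:**
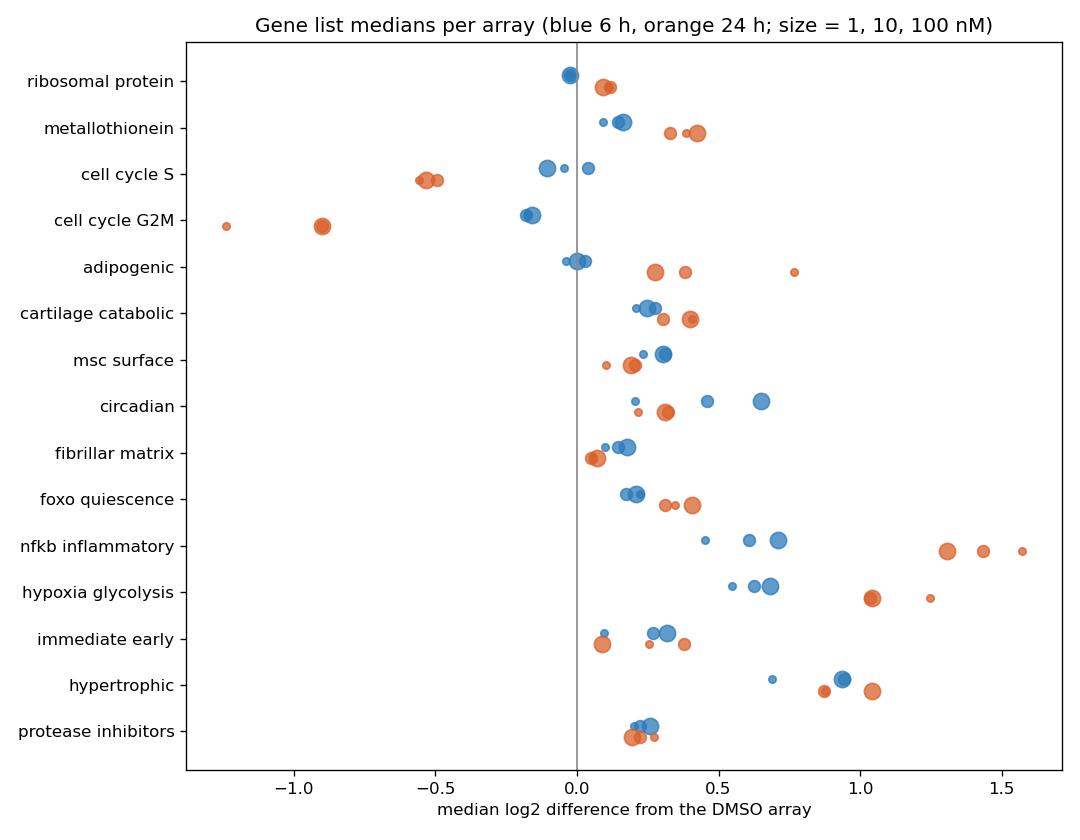
Median log2 difference from the DMSO array (x axis) of the genes in each list that passed at 6 h or 24 h (y axis), 1 point per array, blue for 6 h and orange for 24 h, with point size for 1, 10 and 100 nM. The medians for 24 h lay between -1.24 and -0.90 for the G2/M genes and between 1.31 and 1.57 for the inflammatory genes.

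Both comparisons share the DMSO array, so their likeness is partly built in. Across genes their changes correlated at 0.764, against 0.749 in simulated arrays with no effect, and genes are not independent replicates. The covariance was 0.186 against 0.0216 simulated, a difference of 0.165. Among the calls 587 genes were higher in both and 366 lower in both, where independent lists would share 105 each, and 8 were higher at 6 h and lower at 24 h and 2 the reverse. With 1 vehicle array the control could not be split, so the part of the excess that comes from it is not known. Counted array by array with no test, the genes at least 2-fold from DMSO were 276 at 100 nM, 255 at 10 nM and 170 at 1 nM for 6 h, and 784, 902 and 1202 for 24 h. At all 3 doses 146 genes were at least 2-fold higher and 14 lower at 6 h, and 296 and 313 at 24 h.

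Between 6 and 24 h of kartogenin HES4 had the largest rise and UBASH3B the largest fall. HES4 rose 12.2-fold (3.61 ± 0.18, adjusted p = 0.0129), HSPA6 by 3.11 ± 0.17, CLEC2B by 2.60, C11orf96 by 2.37, ZNF595 by 2.36, DDIT3 by 2.35 ± 0.07, the cyclooxygenase PTGS1 by 2.24, MCHR1 by 2.18, the chemokine CCL26 by 2.18 and OSER1 by 2.16. UBASH3B fell by 2.96 ± 0.18 (adjusted p = 0.0129). The change was -2.10 for CCNYL1, -2.08 for ASPM, which organises the mitotic spindle pole, -2.01 for LCMT2, -1.93 for CEP78, -1.93 for CRYBG1, -1.90 for GSPT2, -1.89 for IFIT5, -1.87 for CSTF2T and -1.85 for NEDD9, a scaffold protein of cell adhesion. In all 3367 genes passed, 928 higher and 2439 lower, and 90 and 230 of them changed at least 2-fold. The median over all genes was -0.11, which centring on array medians moved to 0.01, and the split was then 1781 higher and 2028 lower. With each dose a pair of arrays, leaving out the 10 nM or the 1 nM pair left 0 genes past the threshold, and leaving out the 100 nM pair left 1195. The latter ended the calls of PTGS1, ASPM and IFIT5 (adjusted p = 0.0629, 0.0507 and 0.054). With no filter on dim genes 96 passed, and of the genes named in this paragraph CCL26 alone kept its call (adjusted p = 0.0438). The change of CEP78 was -1.01 with the actin ratio in place of dose and -1.09 without the 24 h arrays at 10 and 1 nM, and did not pass (adjusted p = 0.145 and 0.0505). The count was 1315 with the actin ratio in place of dose, and 2281 without the 24 h arrays at 10 and 1 nM, of which 1791 were among the 3367. The last fit sets 1 array at 24 h against 3 at 6 h with no dose term, and the fit of all 6 arrays with no dose term gave 4149.

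Of 18 G2/M genes 15 fell and 0 rose with time (16 fell adjusted over the list alone), with CENPF at -1.40 and CCNB1 at -1.24 (camera adjusted p = 0.000251, and adjusted p = 0.75 with an estimated correlation). Of 16 S-phase genes 9 fell (11 adjusted over the list alone), with MCM5 at -0.88 (camera adjusted p = 0.0135, and adjusted p = 0.772 with an estimated correlation). Of 10 NRF2 and AHR genes 8 fell (also 8 adjusted over the list alone), with the cystine transporter SLC7A11 at -1.15 and TXNRD1 at -0.95 (camera adjusted p = 0.0159, and adjusted p = 0.772 with an estimated correlation). Of 15 inflammatory genes 8 rose and 2 fell (10 and 2 adjusted over the list alone), with IL11 at 1.99 and CXCL8 at 1.73. Of 16 adipogenic genes 6 were tested and 4 rose (also 4 adjusted over the list alone), with CEBPD at 0.80. Both lists had camera adjusted p = 0.000712 (adjusted p = 0.772 with an estimated correlation). The hypoxia list (6 of 17 higher, also 6 adjusted over the list alone, SLC2A3 at 1.02) had camera adjusted p = 0.011 (adjusted p = 0.772 with an estimated correlation). Its median was 0.036, at percentile 80.2 of matched random lists. The FOXO list (5 higher and 3 lower of 18, 7 and 3 adjusted over the list alone, FBXO32 at 1.01) and the metallothionein list (4 higher and 1 lower of 8, 5 and 1 adjusted over the list alone) had camera adjusted p = 0.00747 and 0.00633 (both adjusted p = 0.75 with an estimated correlation). The ribosomal list (1 of 13 higher, 0 adjusted over the list alone) had camera adjusted p = 0.000712 (adjusted p = 0.764 with an estimated correlation). Its median lay at percentile 93.1 of matched random lists. Apart from the hypoxia list, the other lists that passed for time lay at 0.34 or lower or at 99.4 or higher. The calls of the hypoxia, metallothionein and ribosomal lists were lost with quantile normalization. That of the hypoxia list was also lost with no filter on dim genes (adjusted p = 0.0634). Among lists that did not pass, mean and median differed in sign for the interferon and hypertrophic genes, and the camera direction was upward against a negative median for the chondrogenic, immediate early, p53 and surface marker lists. Beside these groups the actin ratio moved from 3.94 to 4.74 at 6 h to 5.42 to 13.55 at 24 h.

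No gene followed dose across both times in the limma test, where 0 of 9383 genes passed, the smallest adjusted p was 0.736 and 603 genes had an unadjusted p under 0.05. The genes with the smallest p did not pass: DENND2C, CCL26 and KLHL8 had slopes of 0.29, 0.34 and 0.21 per 10-fold dose, and AKR1C3, a steroid-converting aldo-keto reductase, MRE11 and STARD10 had slopes of -0.22, -0.16 and -0.33 (adjusted p = 0.736 for each). CCL26 at 24 h was 7.37 at 100 nM and 6.62 at 1 nM. The slope did not differ between times for any gene by the same limma test, with 0 past the threshold, 1045 at an unadjusted p under 0.05 and a smallest adjusted p of 0.412. The smallest p belonged to PHLPP2, NAP1L3 and TMEM168, whose slopes were 0.64, 0.57 and 0.56 higher at 24 h, and to ZNF528, ARHGAP30 and TCTN2, at -0.68, -0.66 and -0.54. No list passed for dose (with no filter on dim genes the fibrillar matrix list did, adjusted p = 0.0032), and the lowest camera adjusted p was 0.0652 for the adipogenic genes, whose median slope was -0.08.

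Genes of cartilage and of the CBF-beta pathway were read out whatever their values. SOX9 rose 1.95-fold at 6 h (0.96 ± 0.13, adjusted p = 0.0144) and 1.80-fold at 24 h (0.85 ± 0.13, adjusted p = 0.00557). With 1 array at 24 h, without those at 10 and 1 nM, the 24 h change was 0.84 and did not pass (adjusted p = 0.0712). With the actin ratio as a covariate it was 0.86 and did not pass (adjusted p = 0.0755). Its 2 probe sets had different courses. The brighter went from 8.60 with DMSO to 9.56 ± 0.18 (SD over 3 doses) at 6 h and 9.45 ± 0.01 at 24 h, and the other from 7.83 to 8.05 ± 0.18 and 9.13 ± 0.46. The 24 h values of the second were 8.63, 9.21 and 9.55 at 100, 10 and 1 nM, in the order of the actin ratio. With the mean of the probe sets the 6 h change of SOX9 was 0.59 (adjusted p = 0.115), and the 6 h call also ended without the 10 nM array at 6 h (adjusted p = 0.063) and with the 6 h arm and DMSO alone (adjusted p = 0.0637). CBFB, which encodes CBF-beta, stood at 9.95 with DMSO, 10.30 ± 0.04 at 6 h and 9.98 ± 0.14 at 24 h. Its difference at 6 h did not pass (0.35 ± 0.11, adjusted p = 0.107), though it did when only the 6 h arm and DMSO were fitted (adjusted p = 0.0484), and from 6 to 24 h it fell by 0.31 ± 0.07 (adjusted p = 0.0369), a call lost when the median of each array was centred (adjusted p = 0.0967). With the actin ratio in place of dose that change was -0.12 and without the 24 h arrays at 10 and 1 nM -0.15, and neither passed (adjusted p = 0.368 and 0.109). RUNX2, the bone and hypertrophy regulator, fell by 0.45 ± 0.07 from 6 to 24 h (adjusted p = 0.0186) on its brightest probe set. The means of its dimmer probe sets above the lowest value did not fall. One went from 4.74 ± 0.27 at 6 h to 5.07 ± 0.25 at 24 h (SD over 3 doses). Another went from 5.83 ± 0.67 to 5.92 ± 0.20, and the rest lay at the lowest value on every array. The time calls of CBFB, RUNX2, ACAN, ADAMTS5 and TIMP3 each ended when the 100 nM pair was left out, where 1195 genes still passed. Without the 10 nM or the 1 nM pair 0 genes passed, so those fits say nothing particular about these genes. ADAMTS5 went from 9.38 ± 0.11 at 6 h to 8.77 ± 0.29 at 24 h (SD over 3 doses). With the actin ratio in place of dose its time change was -0.20 and did not pass (adjusted p = 0.347). Without the 24 h arrays at 10 and 1 nM that change was -0.37.

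ACAN, the large proteoglycan of cartilage, fell by 0.56 ± 0.08 from 6 to 24 h (adjusted p = 0.017) and was 0.38 lower than with DMSO at 24 h (log2 change -0.38 ± 0.11, adjusted p = 0.0371, and adjusted p = 0.145 after median centring). COMP, a cartilage matrix protein, rose by 0.53 ± 0.13 at 24 h (adjusted p = 0.0201). The aggrecanase ADAMTS5 fell by 0.97 ± 0.21 at 24 h (adjusted p = 0.0165), and with the actin ratio as a covariate its change was -0.38 (adjusted p = 0.214). Of its other bright probe sets, one stood at 9.33 with DMSO, 9.47 ± 0.12 at 6 h and 8.29 ± 0.20 at 24 h (SD over 3 doses). Another stood at 8.57, 7.89 ± 0.12 and 7.53 ± 0.25. Both were lower than with DMSO at 24 h but differed in direction at 6 h. Among the metalloproteinase inhibitors TIMP1 rose by 0.33 ± 0.09 at 24 h (adjusted p = 0.0279) and TIMP2 by 0.28 ± 0.06 at 6 h (adjusted p = 0.0361). The TIMP2 call was lost with the mean of its probe sets (a change of 0.18), with median centring and with the actin ratio as a covariate. Leaving out any 1 of the 6 h arrays also ended it. The dimmer TIMP2 probe sets went from 8.73 and 13.10 with DMSO to 8.79 ± 0.02 and 13.31 ± 0.02 at 6 h (SD over 3 doses). TIMP3 fell by 0.29 ± 0.06 from 6 to 24 h (adjusted p = 0.0304), but the mean of its probe sets changed by 0.030. With the actin ratio in place of dose the change of TIMP3 was -0.13 and without the 24 h arrays at 10 and 1 nM -0.17 (adjusted p = 0.287 and 0.134). With the actin ratio as a covariate the 24 h changes of TIMP1 and ACAN were 0.24 and -0.45 and did not pass (adjusted p = 0.299 and 0.165). Without the 24 h arrays at 10 and 1 nM they were 0.30 and -0.45 and did not pass (adjusted p = 0.0913 and 0.11). Fitted with only their own arm and DMSO, COMP, TIMP1, ACAN and ADAMTS5 at 24 h and TIMP2 at 6 h did not pass (adjusted p = 0.109, 0.0856, 0.0639, 0.0992 and 0.0537). COL2A1 and PRG4 lay at the lowest value on all 7 arrays, and MMP13 had a single value of 2.26 on all of them. COL10A1 lay between 2.50 and 3.83, and no change could be read for these 4 genes.

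**Figure D3:**
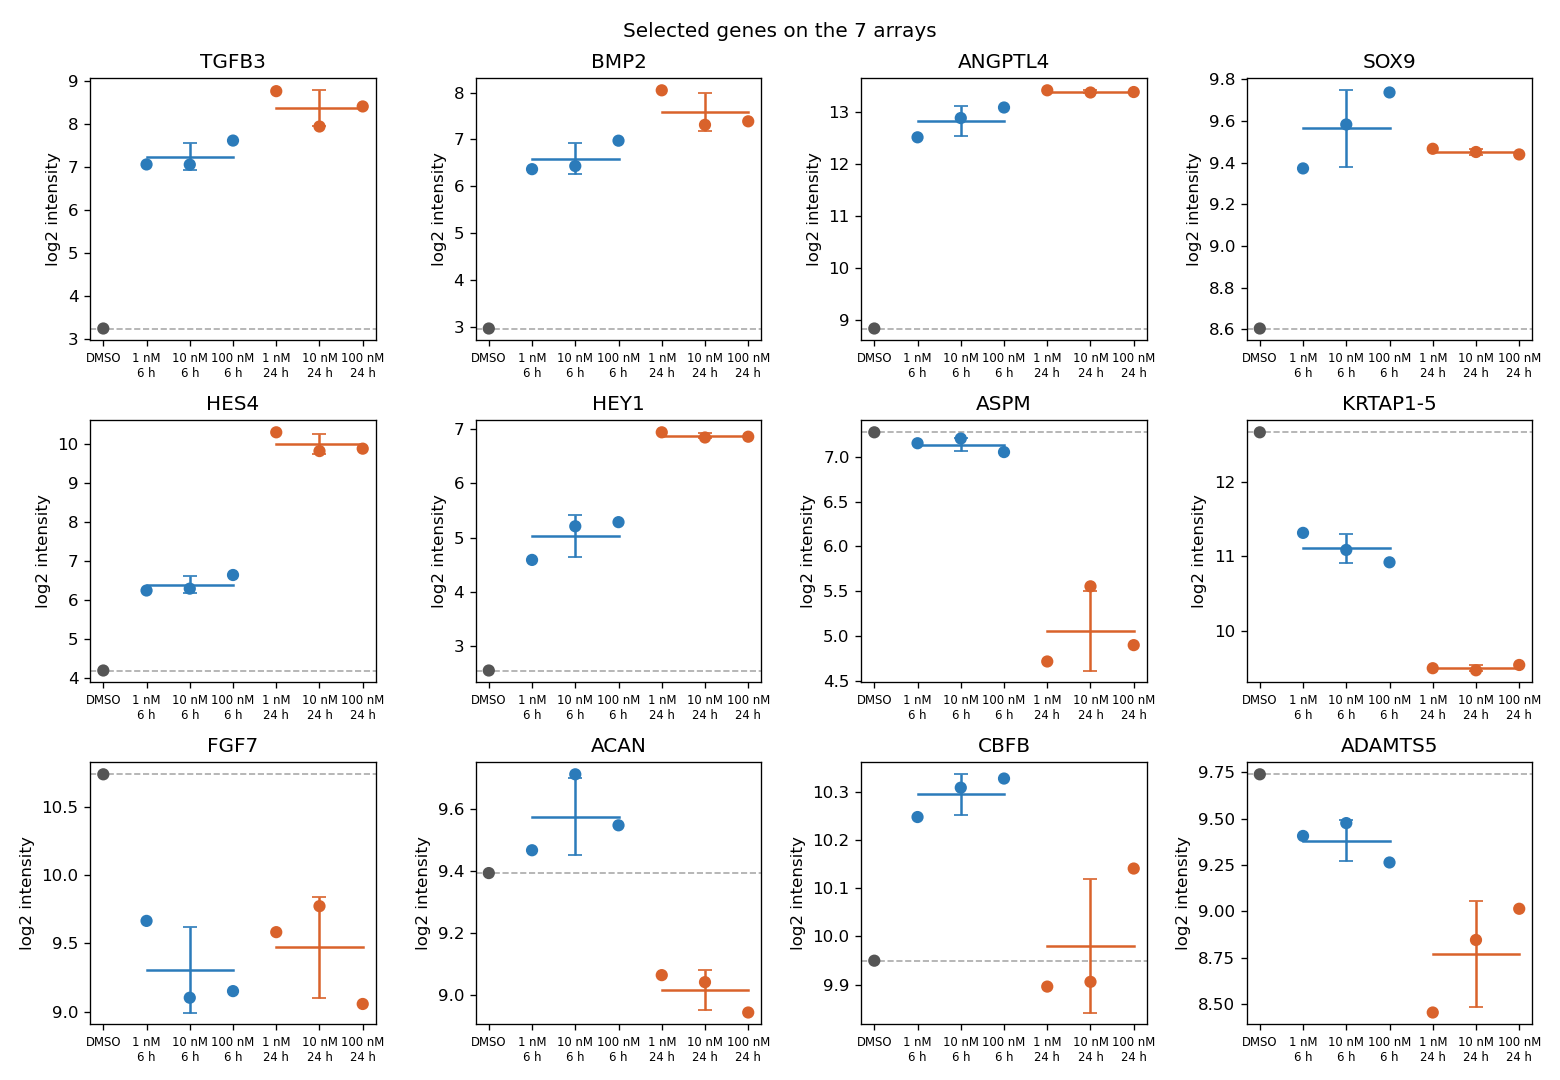
Log2 intensity (y axis) of 12 named genes on the 7 arrays (x axis), grey for DMSO, blue for 6 h and orange for 24 h, with lines at the mean of the 3 doses, bars for the SD over doses and a dashed line at the DMSO value. The y axes differ between genes and do not start at 0, and HES4 went from 4.19 with DMSO to 10.00 at 24 h.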

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

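The tests on second probe sets and on other groupings of the arrays were set before their results were seen, and the tests on dose ratios, on the slope across pairs and on the actin ratio were chosen after. No combination of dose and time held the 4 arrays that the test of outlying values within groups needs.

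The DMSO comparison went opposite ways at the 2 times for 914 genes with a time effect, with every 6 h array on one side of the vehicle and every 24 h array on the other. Of these 675 were above DMSO at 6 h and below it at 24 h, and 239 the reverse. They were counted without centring on array medians, which moved the median time change over all genes from -0.11 to 0.01. Genes called against DMSO at both times in opposite directions were few, 8 higher then lower and 2 the reverse. The difference between the times passed the test of the time effect, while for RUNX2 the difference from DMSO passed at neither time and for CRYBG1 and ACAN at 24 h alone. The 914 include CRYBG1, with a 24 h minus 6 h difference of -1.93 ± 0.13, ACAN at -0.56 ± 0.08 and RUNX2 at -0.45 ± 0.07. Each is read from 1 probe set, and the means of the dimmer RUNX2 probe sets above the lowest value did not fall from 6 to 24 h. A further bright ACAN probe set, at 8.79 with DMSO, lay below that at 100 nM and 6 h (8.70). At 10 and 1 nM and 6 h it lay above (8.87 and 8.88). In all 20 of the genes eligible to be named went opposite ways, also ACTB, COL1A2, COL5A1, ENG, FASN, PDGFRA, RECK, SKIL, SLC30A1, STARD4, TLE3, VCAM1 and VCL (above, then below) and CEBPD, ISG15, KLHL24 and RPL30 (below, then above). Among the 20 the lowest adjusted p against DMSO at 6 h was 0.0797, for CRYBG1, so none passed there. At 24 h some passed and others, such as FASN and RECK, did not (adjusted p = 0.252 and 0.147).

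The control probe sets, outside the gene comparisons, differed from their DMSO level on several arrays. The actin 3' to 5' ratio reached 13.55 on the 1 nM array at 24 h, against 3.22 with DMSO. BioB spike-ins were 3.35 times the DMSO level on that array, and the 18S control was 1.32 times the DMSO level on the 10 nM array at 24 h, 1.14 times on the 1 nM array at 24 h and 0.156 to 0.241 times on the other 4.

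The time effect ran alongside a change in array quality. Over 953 called genes with a second bright probe set the median ratio of second to main change was 0.715 (95% bootstrap interval 0.646 to 0.78). A ratio of at least 0.5 had been set to count against 3' bias, but that was wrong, since probe positions are not held and a second probe set nearer the 5' end would lose as much signal or more, so 3' bias stays open. The actin ratio moved least in the 100 nM pair. If each gene's change followed the log2 actin ratio, that pair would follow the other pairs with a slope near 0.232. Over 9383 genes the slope was 0.673 (0.658 to 0.685). That interval, like those of the second probe set ratios, resamples genes and leaves out the spread between arrays. With 1 pair at 100 nM that spread is not known. The slope test replaced a share among called genes (0.845) after that share was seen, since calling favours equal shares. Its bounds were set at that point. Part of the excess at 10 and 1 nM may still be technical, and a response to treatment and longer culture cannot be separated here. Of the 10 splits of the 6 arrays into 3 and 3, the real one alone gave 3367 genes, 1 of 10, and the highest other gave 0, too few splits for a share under 0.05.

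The 6 h difference from DMSO rests on 1 vehicle array. Noise of single probe sets on it would not carry over to others, but over 281 called genes the median ratio of second to main change was 0.666 (0.589 to 0.773), which argues against it. A difference of culture or handling of the vehicle that has nothing to do with dose would give 1 nM the same change as 100 nM, and the median ratio was 0.856 (quartiles 0.76 and 0.982, over genes whose calling favours equal doses), between the values that would count for or against, so handling, time in culture and a response already near its maximum at 1 nM cannot be told apart. Taking each of the 4 arrays as the lone one, DMSO alone gave 1080 genes (1 of 4), with 0 as the highest other, and at 24 h it alone gave 3886 (1 of 4), with 3 as the highest other. Neither set of 4 can give a share under 0.05.

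At 24 h the arrays lay farther from DMSO the lower the dose. Of the 200 genes with the steepest slope only 9 had a second bright probe set, with a median ratio of second to main slope of 0.245 (-0.109 to 0.454), too few, and with no probe positions, to settle whether 3' bias may underlie it. The actin ratio at 1 nM was 2.50 times that at 100 nM and fell in the order of dose, so array quality and dose cannot be told apart with 1 array each. For the trend over both times the real ordering of dose gave 0 genes, so all 18 orderings had to give as many and the test could not decide. The highest other also gave 0, and 18 orderings are too few for a share under 0.05.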

How the results depend on the processing

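Each result was recomputed with 1 choice changed at a time, except that for the time effect the actin ratio took the place of dose and the fit without the 10 and 1 nM arrays at 24 h had no dose term. Settings chosen after seeing the data were the actin ratio as a covariate, the fits without the 10 and 1 nM arrays at 24 h and the dose trend at 6 h alone. The time effect is paired by dose, and with no dose term its count was 4149.

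For the time effect the count of 3367 became 96 with no filter, 320 with a log2 change of at least 1, 1315 with the actin ratio in place of dose and 0 to 1195 when a dose pair was left out (0 without the 10 nM or the 1 nM pair). With fewer pairs 1 residual degree of freedom remains. With quantile normalization 1450 rose and 2167 fell, and with median centring 1781 and 2028, against 928 and 2439. For 6 h against DMSO the count of 1080 became 200 at a log2 change of at least 1 and 190 to 1249 when an array was left out, lowest without the 10 nM array at 6 h. For 24 h against DMSO the count of 3886 became 6503 over all probe sets, 867 at a log2 change of at least 1, 1593 with its own arm and DMSO only and 1445 with the actin ratio as a covariate. It was 3142 to 4296 when an array was left out. With quantile normalization 1878 rose and 1994 fell there. The cause was not tested except where fewer arrays, more probe sets or a stricter threshold set it. The dose trend and its difference between times stayed at 0 under every alternative run.

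Genes at least 2-fold from DMSO on 1 array, 276, 255 and 170 at 6 h for 100, 10 and 1 nM and 784, 902 and 1202 at 24 h, became 910, 845, 570, 2155, 2416 and 2838 at 1.5-fold, and 140, 145, 98, 472, 509 and 694 with the mean of all probe sets. Of the lists, 9 passed for time, 9 for 6 h and 12 for 24 h, and with an estimated correlation 0, 0 and 0 did. Quantile normalization left 6 for 24 h. With no filter 1 list, fibrillar matrix, passed for dose.

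For the genes open to naming, each counted once per alternative, 1933 results for 6 h kept their direction and side of the threshold, 208 lost the call and 69 gained it. For 24 h these were 2044, 149 and 38, and for time 1308, 488 and 53. With the mean of all probe sets the time changes of TIMP3 and RECK turned to 0.030 and 0.036, and no other of these genes that had passed reversed. Genes near the lowest intensity of 4.777 have no measurable decrease below it.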

Other observations

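The tests in the paragraphs on dose and on the course of the changes were chosen after the array distances had been seen.

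Further genes of lists that did not pass for time changed singly. The hyaluronan synthases HAS2 and HAS3 fell by 1.37 ± 0.09 and 0.87 ± 0.22 from 6 to 24 h (adjusted p = 0.0129 and 0.0487), while the hyaluronan-binding protein TNFAIP6 was 1.26 ± 0.18 above DMSO at 6 h and 1.64 ± 0.18 at 24 h. Of the stromal markers PDGFRA fell by 0.77 ± 0.05 and ENG by 0.58 ± 0.06 with time, and CD9 rose by 0.82 ± 0.09. Among stress genes DNAJB9 and HSPA5, chaperones of the endoplasmic reticulum, rose by 1.03 ± 0.10 and 0.81 ± 0.07. In the RUNX and CBF-beta list the corepressors TLE4 and TLE3 fell by 0.80 ± 0.15 and 0.76 ± 0.16 and CBFA2T2 rose by 0.74 ± 0.12. Among growth factor genes BMP6 rose by 1.13 ± 0.18, and SKIL, a repressor of SMAD signalling, fell by 1.02 ± 0.14.

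A hypothesis is that the 6 h arrays carry a dose response that the test over both times misses. Over all genes the 100 nM minus 1 nM difference at 6 h correlated with the 10 nM minus DMSO difference, which shares no array with it, at 0.464. A dose effect common to both times would make the 100 nM minus 1 nM differences at 6 and 24 h correlate, and they did so at -0.045. The actin ratio at 24 h also runs with dose. Array quality could therefore hide a shared effect, and this value cannot decide. A dose response at 6 h may account for the correlation at that time, but so may a difference between whole arrays in their distance from DMSO, since each dose is 1 array, and genes are not independent replicates. With the 6 h arrays alone 0 genes passed for dose.

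Another hypothesis is that higher doses slow the change from 6 to 24 h. The 1 nM minus 100 nM difference at 24 h correlated across genes with the 24 h minus 6 h difference at 10 nM, with no array shared, at 0.426. The actin ratio at 24 h has the same order, so a slower course cannot be told apart from array quality. A further hypothesis is that the change from DMSO at 6 h goes on in the same direction to 24 h. The mean 1 and 10 nM difference from DMSO at 6 h correlated with the 100 nM difference between 24 and 6 h at 0.194, between the values set for and against it, which leaves it open.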
